A study of Mus musculus with 8 samples.

How the data were processed

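Poly(A) or total RNA selection is not given in the sources used here; the labels describe total RNA taken with Trizol from frozen mouse intestine (strain C57BL/6) and libraries made with an Illumina TruSeq kit. Each of the 8 libraries came from a separate mouse, 4 named as recipients of Klebsiella and 4 as recipients of Lactobacillus. Libraries are called by group and by the mouse number in the labels. What the mice received beyond these names, for how long, and which part of the intestine was taken are not given in the sources used here.

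Per the submitters' processing notes, the tools were CASAVA, STAR 2.5.1b, HTSeq 0.6.0 and DESeq2 1.10.1, with no role or order. The genome build and annotation are not given in the sources used here. The authors deposited FPKM values (reads scaled by gene length and library size) for 49585 gene identifiers, and the same FPKM values for 15 genes of their own choice; how those 15 were chosen is not given in the sources used here. The 2 tables agreed to a relative difference of 7e-09. The authors also deposited read totals, mapping classes, and the percent of bases at or above quality 30 and the percent of G or C bases per library. Symbols for 49326 identifiers, and gene positions on GRCm38, came from GENCODE release M21; 259 identifiers had no match.

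FPKM values are not counts, so no count model was the main test. For each gene, the values of the libraries were whole multiples of what 1 read is worth, within a relative tolerance of 1e-12, for 26962 of 26963 genes above 0 in at least 2 libraries. The reads recovered in this way came to between 15375480 and 20953595 per library. They cover counting error only, and a common factor of a gene's reads cannot be seen. On simulated data 99.53% of 7676 resolved genes came back exactly.

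Values were analysed as log2(FPKM + 0.5) for the 16865 genes with a mean FPKM of at least 0.5 over the 8 libraries. A log2 change on this scale understates the change of low genes. The groups were compared with limma 3.58.1 in R 4.3.3 (a mean-variance trend, two-sided, Benjamini-Hochberg adjustment), with Klebsiella minus Lactobacillus as the direction and an adjusted p under 0.05 as the threshold. The 40 gene lists were tested with limma's camera at a preset correlation of 0.01 and adjusted over the lists, each with at least 5 tested genes. Camera with an estimated correlation and the fry rotation test were alternatives. Members of a list were also adjusted over the list alone. Single values were compared with a two-sided exact permutation test over 70 assignments of 4 against 4, for which the smallest p is 0.0286. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.

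The 3 comparisons and their tests, the gene lists, the main alternatives and the rule for naming genes were fixed before the data were examined. Some tests of explanations in the closing section were set after values had been seen, as is said there. The rule took the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with groups that do not overlap, filled with the genes of smallest unadjusted p where fewer passed. It also took the authors' 15 genes, up to 4 members of each list, and every member past the threshold over its list alone. Gene models with only a number, and pseudogenes, were not named under the first part. Hoxb6, Car1, Ctrb1, Prss2, Slc10a2, Fabp1, Apoa4 and Alpi were chosen after their values were seen.

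The test was tried on simulated data in which 200 genes were changed by known folds. With the dispersion of each gene taken from these libraries, limma called 22.2% of genes changed 1.5-fold, 46.2% of those changed 2-fold and 75.8% of those changed 4-fold, with 5 false calls among 99. With 1 dispersion for every gene the shares were 1.5%, 29.2% and 98.5%, with 8 false calls among 93. The median residual SD on the log2 scale was 0.224 in the first simulation and 0.301 in the second, against 0.239 in the data. Dispersions taken from so few libraries are uncertain, and genes were drawn independently. The shares are therefore only a rough guide to what could be called here. Camera called a simulated list of 15 genes raised 1.5-fold and 0 of 39 others; the simulated genes were independent of each other, which real list members are not.

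Alternatives were other pseudocounts and filters, 3 rescalings, array weights, a robust variance prior, the mouse number as a block, and each library left out in turn. Voom on the recovered reads, log2 Hoxd13 as a covariate and the removal of 2 pairs of libraries were added after the data were seen.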

Results

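RNA from the intestine of 8 mice was sequenced, 4 recipients of Klebsiella and 4 recipients of Lactobacillus, which are genera of gut bacteria. Between 40455910 and 55447220 reads per library passed the authors' read filter, and between 95.04% and 96.59% of reads mapped. The reads in genes recovered from FPKM came to between 15375480 and 20953595 per library. These sums were computed and leave out genes above 0 in only 1 library. Whether their unit is a single read or a pair of reads was not checked. They are therefore not set against the filtered reads as a share of reads in genes. Over 12 read and mapping statistics the smallest two-sided exact permutation p between the groups was 0.257 (4 against 4 libraries, adjusted p 0.743); at this size a single statistic cannot pass after adjustment. Correlations of log2 values across genes were 0.949 to 0.976 between any 2 libraries, so no library was a copy of another.

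Transcripts of small-intestinal absorption ranged from near absent to abundant. Fabp1 and Apoa4 reached at most 0.44 and 0.0349 FPKM, while Fabp2, a fatty acid binding protein, was at 28.9 to 322 FPKM, Alpi at up to 5.35 and Slc10a2, the ileal bile acid transporter, at up to 6.09. The libraries of a group were not alike in position markers. Hoxb6 was at 40.2 FPKM in Klebsiella replicate 3 and 45.2 in Lactobacillus replicate 2, and between 1.16 and 3.87 in the others. Car1, a carbonic anhydrase, was at 2342 and 2947 FPKM in the same libraries and at most 836 elsewhere. Hoxd13, a homeobox gene of the distal gut, was at 46.3, 3.25, 2.20 and 8.03 FPKM in Klebsiella replicates 1 to 4 and at 43.9, 19.1, 27.3 and 39.2 in Lactobacillus replicates 1 to 4. The pancreatic protease transcript Ctrb1 was at 418 FPKM in Klebsiella replicate 2 and 112 in Lactobacillus replicate 3, and at most 2.99 elsewhere.

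**Figure D1:**
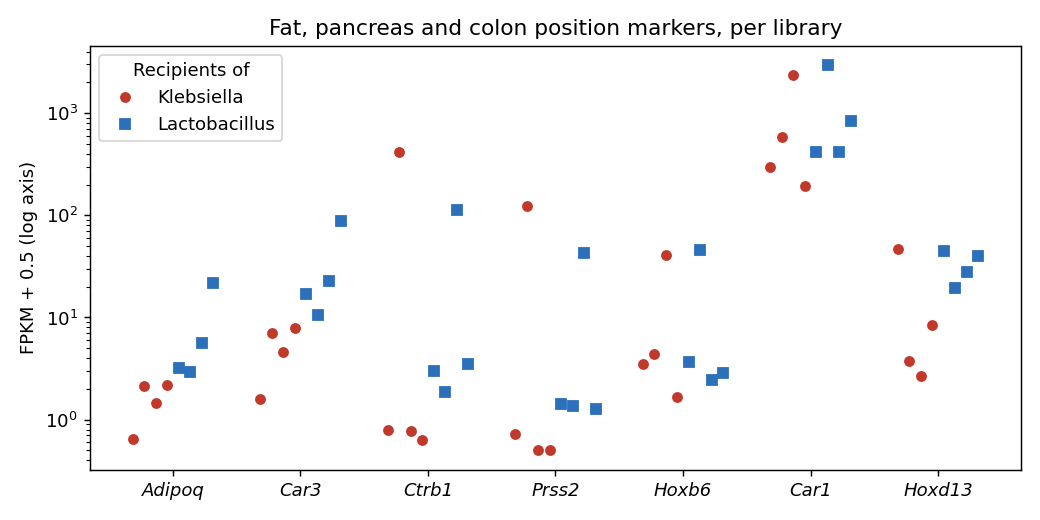
FPKM + 0.5 on a log axis of markers of fat (Adipoq, Car3), pancreas (Ctrb1, Prss2) and position along the gut (Hoxb6, Car1, Hoxd13); each point is 1 library, circles for Klebsiella and squares for Lactobacillus recipients, in replicate order. Ctrb1 stands apart in 1 library of each group, at 418 and 112 FPKM, and so does Hoxb6, at 40.2 and 45.2 FPKM.

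The first comparison asked which genes differed between the recipients. The genes nearest to a difference included transcripts of tuft cells, the chemosensory cells of the gut epithelium. Trpm5, the cation channel of taste transduction, was at 7.68 ± 0.956 FPKM in Klebsiella and 3.91 ± 0.347 in Lactobacillus recipients (SD, n = 4 each), a log2 difference of 0.89 (SE 0.13, limma adjusted p 0.462) from 279 to 405 reads against 161 to 198. Sh2d7, which encodes an SH2 domain protein, was at 3.42 ± 0.544 against 1.32 ± 0.183 FPKM, a log2 difference of 1.11 (SE 0.16, limma adjusted p 0.462). Cldn8, a tight junction claudin, was at 34.7 ± 3.13 against 57.6 ± 11.7 FPKM, a log2 difference of -0.71 (SE 0.14, limma adjusted p 0.774).

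None of these passed the threshold. Of 16865 genes tested with limma, 0 were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.462. At an unadjusted p under 0.05 there were 1024 genes, 430 higher and 594 lower in Klebsiella recipients, where 843 are expected by chance. That count was 572 without Lactobacillus replicate 3, 2009 without Lactobacillus replicate 1 and 1828 without Klebsiella replicate 3. Voom on the recovered reads called 0 genes, with 1020 at an unadjusted p under 0.05. The 2 groups did not overlap for 505 genes, or 3.0%, where chance gives 2.9%. Of the 1024 genes 42.0% were higher, and 58.2% of the 1017 genes at an unadjusted p under 0.05 when FPKM was rescaled to a constant total.

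The other genes of smallest unadjusted p that were higher in Klebsiella recipients did not pass either. Sh2d6 had a log2 difference of 0.73, Muc4 of 0.92, Hilpda, a lipid droplet gene, of 0.73, Ccl11, the eosinophil chemokine eotaxin, of 0.66 and Igkv8-27 of 1.42. Alas1, the first enzyme of haem synthesis, had a log2 difference of 0.52, Lpgat1 of 0.49, Galnt5 of 0.48 and Nfe2l2, the transcription factor NRF2, of 0.40. Mir7026, a microRNA gene within Ep400, had a log2 difference of 2.25 (3.52 with a pseudocount of 0.1) but at most 5 reads in any library. On the lower side, the log2 differences were -3.12 for Ighv1-22, -1.70 for Ighv2-9-1, -2.83 for Igkv4-72, -0.89 for AI854703, -0.81 for Ybx2 and -0.58 for Tcf7l1, a Wnt pathway repressor (-0.38 with log2 Hoxd13 as a covariate). They were -0.43 for Cdpf1, -0.33 for Smim22, -0.55 for Zan, which overlaps Ephb4, and -0.50 for Prdm9. Mir199a-1, which lies within Dnm2, had a log2 difference of -0.98 and between 1 and 3 reads. Reads of these microRNA genes cannot be told from those of the genes around them.

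On GRCm38, Trpm5 lies on chromosome 7 from 143069153 to 143094642 and overlaps Tssc4. Sh2d7 lies on chromosome 9 from 54538984 to 54545020 and overlaps Cib2, Muc4 on chromosome 16 from 32735886 to 32782391 and overlaps Muc20, and Cldn8 on chromosome 16 from 88560828 to 88563183. Whether reads of overlapping genes were shared by strand is not given in the sources used here.

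The second comparison asked whether groups of genes moved together. Tuft cell genes were higher in Klebsiella recipients: 14 of 15 tested members had a positive log2 difference, with a median of 0.49 (camera adjusted p 1.67e-08). The adjusted p was 0.441 with an estimated correlation. Adjusted over the list alone, 7 members were higher and 0 lower, and over all genes 0 passed. They were Trpm5 and Sh2d6, Dclk1, a kinase that marks tuft cells, Pou2f3, their lineage transcription factor, Alox5, the leukotriene-forming lipoxygenase, Avil and Rgs13. Dclk1 was at 8.24 ± 0.988 against 5.73 ± 0.7998 FPKM and Pou2f3 at 1.00 ± 0.135 against 0.545 ± 0.120 FPKM (SD, n = 4 each).

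**Figure D2:**
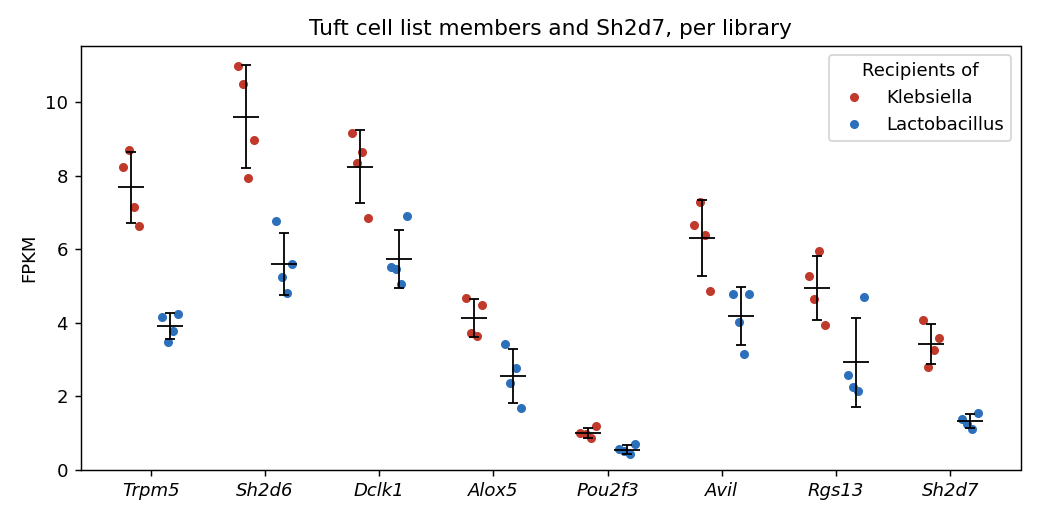
FPKM per library of the 7 tuft cell list members past the threshold over the list alone, and of Sh2d7; points are libraries, the black line is the mean and the bars are the SD (n = 4 per group). The 4 Klebsiella libraries lie above the 4 Lactobacillus libraries for Trpm5, Sh2d6, Alox5, Pou2f3, Avil and Sh2d7. The groups overlap for Dclk1 and Rgs13. Means are 7.68 against 3.91 FPKM for Trpm5 and 3.42 against 1.32 FPKM for Sh2d7.

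Transcripts of fat were lower in Klebsiella recipients: 14 of 15 tested members of the adipose list had a negative log2 difference, with a median of -0.49 and a mean of -0.95 (camera adjusted p 1.24e-05). The adjusted p was 0.956 with an estimated correlation, and 0 members passed over the list alone. Car3, an adipocyte carbonic anhydrase, was at 4.77 ± 2.83 against 34.1 ± 36.1 FPKM, and the hormone gene Adipoq at 1.11 ± 0.733 against 7.83 ± 8.89 FPKM (SD, n = 4 each). Cfd had a log2 difference of -2.62 and Plin1 of -1.81 (-3.19 with voom). Lactobacillus replicate 4 held the most Car3, 87.7 FPKM against 10.1 to 22.2 in the other Lactobacillus libraries, and without it the median of the list was -0.28; with log2 Hoxd13 as a covariate it was -0.74.

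Stress and sterol lists were called higher in Klebsiella recipients. Of the heat shock and unfolded protein response list, 24 of 27 members had a positive log2 difference (camera adjusted p 1.24e-05; adjusted p 0.956 with an estimated correlation), with Xbp1 at 0.38, Herpud1 at 0.30 and Atf4 at 0.60 (0.91 with log2 Hoxd13 as a covariate). The highest mean log2 score of this list was nevertheless in Lactobacillus replicate 1, at 6.66 against 6.12 to 6.34 in Klebsiella libraries and 5.60 to 5.905 in the other Lactobacillus libraries. The list's median of 0.22 was 0.43 without that library, 0.13 without Lactobacillus replicate 3 and 0.14 without the pair of libraries with high Ctrb1. Of the cholesterol synthesis list, 21 of 25 were positive (camera adjusted p 0.000435; adjusted p 0.956 with an estimated correlation), with Cyp51 at 0.61 (0.38 without Lactobacillus replicate 4). Of the immediate-early and handling stress list, 19 of 24 were positive (camera adjusted p 0.00231; adjusted p 0.956 with an estimated correlation), with Ccn2 at 0.56 (0.88 with the covariate) and Ier3 at 0.92. Over the lists alone 0 members of these 3 lists passed. Mean log2 scores of the cholesterol list were 5.43 to 5.74 in Klebsiella replicates 1, 2 and 4 and Lactobacillus replicate 1. They were 4.66 to 5.23 in the other libraries, Klebsiella replicate 3 among them. The immediate-early scores were higher in the same libraries, at 5.19 to 6.62 against 4.16 to 5.17. That gap was very narrow, between 5.193 in Lactobacillus replicate 1 and 5.171 in Lactobacillus replicate 3. So neither of these lists split by group. The cholesterol median of 0.33 was 0.14 without Lactobacillus replicate 4, where the call ended (camera adjusted p 0.234), 0.22 without Klebsiella replicate 1, 0.51 without Klebsiella replicate 3, 0.57 with the covariate and 0.58 without the pair with high Hoxb6. The immediate-early median of 0.48 was 0.072 without Klebsiella replicate 2 and 0.24 without the pair with high Ctrb1, where the call ended (camera adjusted p 0.432 and 0.0800), 0.32 without Lactobacillus replicate 4, 0.89 without Klebsiella replicate 3, 0.88 without the pair with high Hoxb6 and 0.77 with array weights.

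Cytokine, muscle, cell cycle and mucus lists were also called higher in Klebsiella recipients. For innate cytokines and chemokines 8 of 9 tested members were positive (camera adjusted p 0.00231; adjusted p 0.956 with an estimated correlation), with log2 differences of 1.23 for Ptgs2 (0.79 without the pair of libraries with high Ctrb1), 1.61 for Ccl2 and 1.45 for Ccl7 (2.62 and 2.66 with log2 Hoxd13 as a covariate). For smooth muscle 16 of 17 were positive (camera adjusted p 0.0121; adjusted p 0.956 with an estimated correlation), with Flna at 0.37 (0.084 to 0.57 over the alternatives), and for proliferation 26 of 30 (camera adjusted p 0.0437; adjusted p 0.956 with an estimated correlation), with Plk1 at 0.28 (0.12 to 0.40 over the alternatives). For goblet cells and mucus 14 of 21 were positive (camera adjusted p 0.0437; adjusted p 0.956 with an estimated correlation). Its 2 members past the threshold over the list alone were membrane mucins that went opposite ways, Muc4 at 47.6 ± 10.2 against 24.97 ± 5.95 FPKM and Muc13 at 434 ± 36.8 against 592 ± 65.4 FPKM (SD, n = 4 each, limma). Spdef and Ern2 had log2 differences of 0.88 and 0.35. The cytokine median of 0.74 was 0.48 without the pair of libraries with high Ctrb1, where the call ended (camera adjusted p 0.0547), 0.23 with no filter on low values and 1.42 with voom. The mean log2 score of the cytokine list was 1.884 to 2.555 in Klebsiella replicates 1, 2 and 4 and Lactobacillus replicate 1. It was 0.657 to 1.271 in the other libraries, so this list did not split by group either. Nor did smooth muscle, whose lowest score, 5.506, was in Klebsiella replicate 4. The highest proliferation score, 4.887, was in Lactobacillus replicate 1. Goblet cell scores also overlapped, with 7.492 in Klebsiella replicate 1 and 7.676 in Lactobacillus replicate 1. The estimated correlation between members was 0.93 for smooth muscle and 0.91 for proliferation, so their counts of positive members are not independent signals.

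The goblet cell median was 0.20. The call ended without the pair of libraries with high Hoxb6 (camera adjusted p 0.390, median 0.12) or with high Ctrb1 (0.0573, median 0.18), and without Klebsiella replicates 2 or 3 or Lactobacillus replicate 2 (0.0863, 0.181 and 0.264, medians 0.18, 0.16 and 0.14). It also ended, with medians no smaller, with log2 Hoxd13 as a covariate (camera adjusted p 0.364, median 0.30), with FPKM rescaled to a constant total or by median-of-ratios factors (0.0666 and 0.0656, median 0.23 in both) and with voom (0.0527, median 0.22). The smooth muscle median was 0.28. The call ended with the covariate (camera adjusted p 0.162, median 0.18), without the pair with high Ctrb1 (0.128, median 0.14) or with high Hoxb6 (0.825, median -0.054), and without Klebsiella replicates 1, 2 or 3 or Lactobacillus replicate 2 (0.0769, 0.0982, 0.457 and 0.314, medians 0.24, 0.14, 0.087 and 0.14); the median was 0.68 without Klebsiella replicate 4 and 0.52 with array weights. The proliferation median was 0.17. The call ended without Klebsiella replicates 1 or 4 or Lactobacillus replicates 2 or 4 (camera adjusted p 0.563, 0.557, 0.177 and 0.336, medians 0.091, 0.061, 0.13 and -0.10). It also ended, with medians of 0.15 to 0.20, under 3 rescalings, array weights, the mouse number as a block and voom (camera adjusted p 0.0524 to 0.0786). The median was 0.32 to 0.46 without Klebsiella replicate 3, Lactobacillus replicates 1 or 3 or either pair, and with the covariate.

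In all 9 of 40 lists were called, 8 higher and 1 lower in Klebsiella recipients, and 0 were called with an estimated correlation. Without Klebsiella replicate 4 the count was 15 and without Lactobacillus replicate 3 it was 17. The fry test called 0 lists for a shared change in 1 direction, with a smallest adjusted p of 0.134 for the tuft cell list. Its mixed form, which asks whether members change whatever their signs, called 1 list, again the tuft cell list (fry mixed adjusted p 0.00125).

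**Figure D3:**
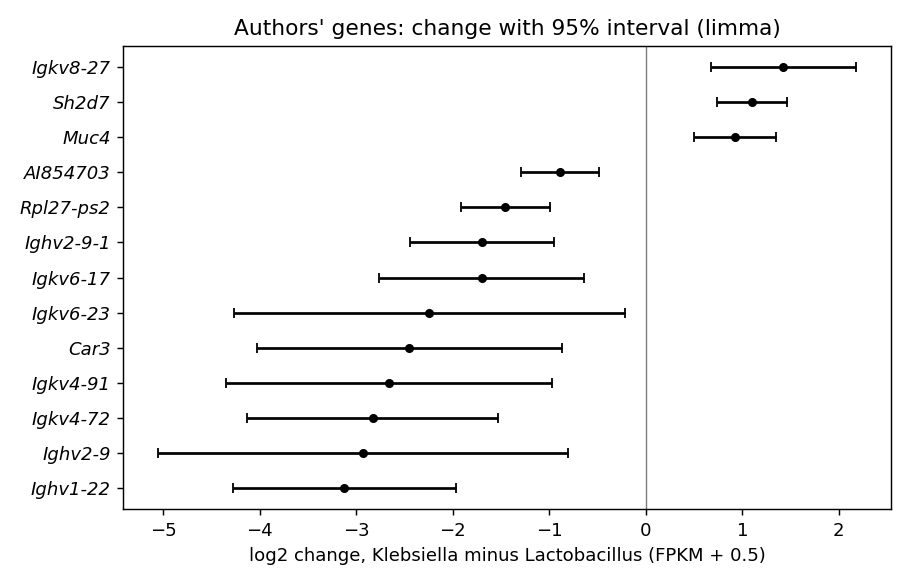
Log2 change of FPKM + 0.5, Klebsiella minus Lactobacillus recipients, of the 13 tested genes of the authors' list; points are limma estimates and bars their 95% intervals from 4 libraries per group. Of these, 3 lie above 0 and 10 below, from 1.42 for Igkv8-27 to -3.12 for Ighv1-22.

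The third comparison took the 15 genes of a table that the authors named as one of differing genes. Of these, 8 were immunoglobulin variable segments, the parts of antibody genes that differ between B cell clones. In Klebsiella recipients 3 of the 15 genes were higher (Sh2d7, Muc4 and Igkv8-27) and 12 lower. Ighv1-22 was at 5.32 ± 2.65 against 56.9 ± 36.5 FPKM and Igkv4-72 at 11.5 ± 7.80 against 81.5 ± 57.3 FPKM (SD, n = 4 each). The log2 differences were -2.93 for Ighv2-9, -2.66 for Igkv4-91, -2.24 for Igkv6-23 and -1.70 for Igkv6-17, and the groups overlapped for the last 3. Igkv6-23 was at 208 and 315 FPKM in Lactobacillus replicates 1 and 2 but at 24.2 and 18.1 in replicates 3 and 4, against 9.79 to 22.99 in Klebsiella libraries, and its log2 difference was -1.41 without the pair with high Hoxb6. The pseudogene Rpl27-ps2 had 0 or 1 reads in Klebsiella and 6 to 13 in Lactobacillus libraries, and its reads cannot be told from those of gene copies with like sequence. Orm1 and Pon1 were below the filter, with means of 0 and 0.0269 FPKM in Klebsiella and 0.478 and 0.573 in Lactobacillus recipients. Orm1 had 0 reads in Klebsiella and 1 to 6 in Lactobacillus libraries, and Pon1 had 0 or 1 against 6 to 26. Car3, described above with the transcripts of fat, is also among the 15 genes. Like Car3, Orm1 and Pon1 were highest in Lactobacillus replicate 4, at 0.883 and 1.342 FPKM.

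With limma 0 of the 13 tested genes passed over all genes, and 13 passed adjusted over the list alone, with a largest adjusted p of 0.0337. How the list was chosen is not given in the sources used here; if it was chosen on these samples, as the table's name implies, the second count is not independent evidence. Variable segments made up 8 of the 13 tested genes and 182 of all 16865.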

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

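The tests of position along the gut, of carried-over fat, of Lactobacillus replicate 4 alone and of total plasma cell RNA were set after the values they use had been seen; the other tests here were set before.

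The tuft cell list was the list with the smallest p. A camera p as small for this list came up in 1 of the 35 splits of the libraries, the real one, with -log10 p of 9.38 against 6.12 at most in the others. The list was singled out from 40, however, and in 33 of the 35 splits some list had a p as small, with a -log10 p of up to 27.2, so chance is not excluded once that choice is counted. Position along the gut is not settled. The difference of the mean tuft score was 0.42 (SE 0.13) with log2 Hoxd13 as a covariate and 0.42 without. However, Hoxd13 is a single marker and was partly tied to group. It was at 2.20 to 8.03 FPKM in Klebsiella replicates 2 to 4 and at 19.1 to 43.9 in Lactobacillus libraries. Klebsiella replicates 2 and 4 were also low in Hoxb6, at 3.87 and 1.16 FPKM. So this covariate cannot decide the question. A larger share of epithelium stays open, since 15 pan-epithelial genes differed by 0.12 (SE 0.06), between the bounds set for and against it. A difference in tuft cells or their transcripts between the recipients may remain, as a hypothesis found and tested on the same data.

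For the adipose list a camera p as small came up in 3 of 35 splits, with -log10 p of 6.03 for the real one and 7.53 at most, so chance is not excluded. Fat carried over with the tissue stays open: Car3 and the mean of 7 adipocyte genes had r = 0.983 after centring within groups, as any differing amount of fat would give, and where the fat came from was not tested. Over the 8 libraries r was 0.989 (exact permutation p 5e-05) and rho 0.976 (exact permutation p 0.0004), and r was 0.964 without the 2 libraries farthest from the median; 1 relation was computed. Without Lactobacillus replicate 4 the difference of the mean adipose score was -0.65 (SE 0.24) in place of -0.95, which leaves open how far that library accounts for it.

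For the variable segments, as many as the real 18 at an unadjusted p under 0.05 came up in 16 of 35 splits, with 45 at most, so chance is not excluded. The median SD of these segments within groups was 6.47 times that of other genes of like expression, 1.59 against 0.246 on the log2 scale, as antibody repertoires of single animals would give. For total plasma cell RNA, the authors' 8 segments had a median log2 difference of -2.45, with 1 higher. Igha, Igkc and Jchain had a mean of -0.24 (SE 0.06 over the 3 genes). The 8 come from a list of differing genes, so that gap alone decides nothing. All heavy chain segments summed to 1324 to 1554 FPKM in Klebsiella replicates 1 to 3, 6526 in replicate 4 and 1208 to 2976 in Lactobacillus libraries. Kappa segments summed to 1553 to 2108, 8020 and 1848 to 4713 FPKM. These sums argue against a fall in total plasma cell RNA as large as that of the 8 segments. A smaller difference stays open. A biological difference between the recipients is not tested by this.

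Of 234 groups of 4 libraries checked, 27 held a library far from its other 3. Without the 18 groups of genes given only as levels, most of them chosen after their values were seen, it was 17 of 216, or 7.9%, where chance gives about 1 in 20; the groups share libraries and genes and are not independent. Klebsiella replicate 4 had 90.65% of bases at or above quality 30, against 94.11% to 94.50% in the others of its group. Klebsiella replicate 1 had a mean log2 score of 4.40 for inflammasome and cell death, below the other 3, 46.3 FPKM of Hoxd13 and 0.0349 of Apoa4, against 0 in the other 3. Klebsiella replicate 2 had a score of 6.15 for pancreatic acinar transcripts, with 418 FPKM of Ctrb1 and 124 of Prss2, and 0 FPKM of Rpl27-ps2. Klebsiella replicate 3 had 40.2 FPKM of Hoxb6, 6.09 of Slc10a2 and 0.508 of Ighv2-9. Lactobacillus replicate 1 had a score of 8.15 for mitochondrially encoded genes, the lowest of its group, with 5.87 FPKM of Ptgs2 and 3.35 of Ccl7. Lactobacillus replicate 2 had scores of 5.41 for plasma cells and immunoglobulin and 4.18 for bile acid handling, with 45.2 FPKM of Hoxb6, 6.00 of Slc10a2 and 2947 of Car1. Lactobacillus replicate 3 had a score of 5.13 for pancreatic acinar transcripts, with 112 FPKM of Ctrb1 and 42.4 of Prss2. Lactobacillus replicate 4 had 87.7 FPKM of Car3, 116 of Cfd, 21.04 of Adipoq, 1.34 of Pon1 and 4.70 of Rgs13.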

How the results depend on the processing

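Voom, the Hoxd13 covariate and the removal of 2 pairs of libraries were chosen after seeing the data. Limma called 0 genes under each of the 22 alternatives, with a smallest adjusted p of 0.2502, and 54 named genes kept their sign in all 1185 values compared; Hoxd13 has no value with itself as covariate. Of these genes 16 moved by over 1.5 times under at least 1 alternative: Pou2f3, Avil, Mir7026, Tcf7l1, Rpl27-ps2, Igkv6-23, Plin1, Atf4, Cyp51, Ccn2, Ptgs2, Ccl2, Ccl7, Flna, Plk1 and Hoxb13. The count of called lists, 9, became 14 with the covariate, 0 with an estimated correlation and 0 with fry, and ran from 6 to 17 with single libraries left out, 15 without Klebsiella replicate 4 and 17 without Lactobacillus replicate 3; the cause was not tested. The tuft cell, adipose, and heat shock lists were called under all 22 camera settings at the preset correlation, smooth muscle under 15, goblet cells under 13 and proliferation under 12. The proliferation median ran from -0.10, without Lactobacillus replicate 4, to 0.36 with single libraries left out, and that of smooth muscle was -0.054 without the pair of libraries with high Hoxb6. The authors' genes past the threshold over the list alone numbered 12 or 13 with single libraries left out. For read and mapping statistics a left-out library tests nothing, since with 7 libraries a single one of the 12 cannot pass after adjustment. The count of genes at an unadjusted p under 0.05, 1024, was 1825 with array weights, 1693 with the covariate, 431 without the pair with pancreatic transcripts and 572 to 2009 with single libraries left out; 29.7% to 58.2% of the genes so counted were higher. Mouse numbers do not pair the libraries: deviations of same-numbered mice correlated at 0.19, -0.10, -0.06 and -0.16, and 1 of 4 matched its own number best. With the number as a replicate block 0 genes, 8 lists and 13 of the authors' genes passed. Count tests (edgeR, DESeq2) were not run, since the deposited unit is FPKM, although the recovered reads could have been used. Voom was run on those reads instead. Depth limits genes with few reads, such as Mir7026 with at most 5.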

Other observations

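Of the 31 lists that were not called, 3 held a member past the threshold over the list alone with limma. These were Ccl11 in mast cells and type 2 immunity (7 of 13 members higher in Klebsiella recipients), Nfe2l2 among aryl hydrocarbon receptor targets (4 of 8 higher) and Cldn8 among tight and adherens junctions (11 of 26 higher). Epithelial lists showed 7 of 27 members higher for colonic epithelium, where Hoxb13 had a log2 difference of -0.62 (-0.27 with log2 Hoxd13 as a covariate) and Hoxd13 of -1.97, and 8 of 20 for small-intestinal enterocytes. The numbers were 10 of 22 for enteroendocrine cells, 7 of 18 for crypt stem cells and Wnt targets, 2 of 5 for Paneth cell products and 9 of 24 for bacteria-induced epithelial defence. Among metabolic lists 6 of 19 members were higher for lipid absorption, 7 of 24 for PPAR-alpha targets, 3 of 9 for bile acid handling, 11 of 28 for xenobiotic metabolism, 7 of 20 for NRF2 and oxidative stress, 9 of 20 for the circadian clock and 8 of 15 for mitochondrially encoded genes.

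Among immune lists 9 of 17 members were higher for B cells, 2 of 16 for plasma cells and immunoglobulin, 5 of 22 for T cells and intraepithelial lymphocytes, 4 of 20 for macrophages and dendritic cells and 5 of 6 for neutrophils. The numbers were 11 of 25 for bacterial sensing, 17 of 30 for interferon-stimulated genes, 12 of 26 for interferon-gamma GTPases and MHC class I, 4 of 12 for MHC class II and 6 of 24 for inflammasome and cell death. Among other tissue lists they were 5 of 21 for enteric neurons and glia, 10 of 24 for fibroblasts and matrix, 15 of 17 for endothelium and lymphatics, 0 of 5 for erythroid RNA and 9 of 22 for pancreatic acinar transcripts. The median went against the mean or the camera direction for Paneth cell products, interferon-gamma GTPases, PPAR-alpha targets, the circadian clock, B cells, enteroendocrine cells and pancreatic acinar transcripts. Camera adjusted p over these 31 lists ran from 0.107 to 0.998.

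The count of splits for called genes was set after that count was known. All 35 splits of the 8 libraries into 4 and 4 called at least 0 genes, the real number, which any split must, so this comparison says nothing about chance. The highest other split called 581. That split set Klebsiella replicates 1, 2 and 4 with Lactobacillus replicate 1 against the rest. The scores of the cholesterol synthesis and cytokine lists were higher in the same libraries, and those of the immediate-early list only barely so. This may reflect a structure of the samples other than the group. The split was singled out after the counts were seen, and what sets these libraries apart was not tested. As many genes as the real 1024 at an unadjusted p under 0.05 came up in 7 of 35 splits, with 3645 at most. As many lists as the real 9 were called in 32 of 35 splits, with 20 at most, so chance cannot be excluded for these 2 counts.

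Heavy chain variable segments summed to 6526 FPKM in Klebsiella replicate 4, of which Ighv6-3 took 32.0%, and to between 1208 and 2976 in the other libraries. The leading kappa segment, Igkv9-124, was the same in Klebsiella replicates 1 and 4 and Lactobacillus replicates 1 and 4.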
